A study of Mus musculus with 10 samples.

How the data were processed

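Libraries were made from infundibula of C57BL/6 mice treated for 7 days with recombinant murine prolactin (rmPRL) or saline. Per the labels' protocols, tissue was frozen in liquid nitrogen, RNA was extracted with Trizol and RNeasy columns, and 0.5 ug of total RNA entered the TruSeq Stranded mRNA kit. Per the series text, 2 animals (4 infundibula) were pooled for each library, 5 libraries were made per treatment, and these were sequenced on an Illumina NovaSeq with paired reads of 100 bases at a stated 80 M reads per sample. Groups, replicate numbers and estrous stages were taken from the labels. The labels put 9 libraries at proestrus and 1, rmPRL library 2, at diestrus.

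Per the series text and the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic at a quality threshold of 15 with reads under 20 bases discarded, aligned to mm10 with HISAT2 and SAMtools, and counted with featureCounts, and the authors compared the groups with DESeq2. Versions and the gene annotation were not given in the sources used here. The file holds TPM values that the authors deposited for 54256 genes in 10 libraries, with versioned Ensembl identifiers and gene symbols. Per the file headers the columns are libraries C1 to C5 and T1 to T5, which match the labels' titles. The deposited values carry the name scaled TPM. How they were computed, whether from these counts, and whether they were scaled between libraries was not given in the sources used here. TPM keep no depth, so no count model was run, and the counting error of single genes is unknown.

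Of the 54256 identifiers, 54086 were found in the reference gene table, and 2647 of 2654 rows without a symbol were named from it. Coordinates and overlaps are those of GENCODE vM21 on GRCm38, the assembly that mm10 denotes. The library kit is stranded, but the strand setting of the counting was not given, so genes that overlap on either strand are uncertain. Where a symbol on a list had several rows, the row with the highest mean was used.

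Tests ran in R 4.3.3 with limma 3.58.1. Genes with at least 1 TPM in at least 5 of the 10 libraries were kept (16131 genes), and log2(TPM + 1) values were fitted with limma (lmFit, eBayes with trend and robust estimation), with group as the only term and a Benjamini-Hochberg adjusted p threshold of 0.05. Log2 changes are on the log2(TPM + 1) scale, which understates the change of low genes, and errors beside them are standard errors of the fit. Lists were tested with limma's camera with a correlation estimated from the residuals, for lists with at least 3 tested members. List scores are means of log2(TPM + 1) over tested members, compared with an exact permutation test over all 252 assignments. Single values per library were compared the same way. All tests were two-sided. The ribosomal protein list left out pseudogenes, Rps6 kinases and binding proteins that share the prefix.

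The gene lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold, with a mean of at least 1 TPM in the higher group and groups that did not overlap, leaving out unnamed, Gm-numbered, Rik-named and pseudogene entries. Where fewer passed, a direction was filled to 5 by smallest p. It further named up to 4 members of each list past the threshold, and always Prlr, Stat5a, Stat5b, Cish, Socs2, Esr1, Pgr, Foxj1, Ovgp1 and Pax8. Other members of lists are given as examples of their list and were chosen after their values were seen. Of the genes past the threshold, 1 is not reported here.

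The gene test was tested on simulated data with the 16131 genes and the spread of these libraries, in which 200 genes were changed. It called 58.3% of genes changed by 0.5 on the log2 scale, 89.0% of those changed by 1 and 97.6% of those changed by 2, and 5.17% of its calls were false. In these simulations the noise was drawn independently for each gene. With no genes changed, at most 1 gene was called in 20 such simulations, and 0 in 20 that kept the correlation between genes. Splits of the real libraries gave up to 344 genes, so the simulated false rate may not hold for them. The list test called a shift of 0.5 in all STAT5 targets in 100% of 20 simulations and in MHC class II genes in 55%. Alternatives were other pseudocounts and filters, TMM and quantile scaling, a rescaling without mitochondrial genes and the 50 highest genes, array weights, limma without trend and robust estimation, the replicate number as a block, leaving out each library in turn, a minimum of 1.5-fold, and other list tests. Added after the data were seen were fits without pairs of libraries that stood apart, with GC content and length trends removed and with a fibroblast covariate, and list tests under the scalings. Figures were drawn with matplotlib.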

Results

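RNA was sequenced from the infundibulum, the funnel-shaped ovarian end of the oviduct that takes up the ovulated egg, of C57BL/6 mice given recombinant murine prolactin (rmPRL) or saline for 7 days. Prolactin is a pituitary hormone that signals through its receptor, Prlr, to the kinase Jak2 and the transcription factors Stat5a and Stat5b. Each group held 5 libraries, and each library pooled 4 infundibula from 2 animals, so that replicates were separate pools of animals. The 5 saline libraries and 4 of the rmPRL libraries were labelled proestrus, and rmPRL library 2 was labelled diestrus. The stated depth was 80 M reads per sample. The values analysed were TPM, transcript levels corrected for length and scaled to a common total, which keep no record of each library's depth, and the columns summed to between 999445 and 999607. The number of genes at 1 TPM or more was 16211 ± 144 (SD, n = 5) in saline and 16216 ± 253 (SD, n = 5) in rmPRL, a difference of 4.6 genes (two-sided exact permutation test, p = 0.968). The 50 genes with the highest means took 19.4% ± 0.638 of the TPM in saline and 20.6% ± 0.491 in rmPRL (SD, n = 5 each, two-sided exact permutation test, p = 0.0238). These genes include mt-Atp8, at means of 6298 TPM in saline and 15494 TPM in rmPRL. This difference is therefore not separate from that of the mitochondrial transcripts given below.

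The comparison of the groups asked which transcripts of the infundibulum changed after 7 days of rmPRL. Of 16131 genes tested, 3 rose and 1 fell at an adjusted p under 0.05 (limma on log2(TPM + 1), Benjamini-Hochberg, two-sided). The largest rise was in a shorter record of Septin2, a filament-forming GTPase of the cytoskeleton, from 30.5 ± 3.16 TPM in saline to 66.9 ± 9.53 TPM in rmPRL (SD, n = 5 each). All 5 rmPRL libraries lay above all 5 saline libraries for this record. Gm17066, a non-coding transcript, rose as well, and Gm22581, a short non-coding record, fell.

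For the shorter Septin2 record (ENSMUSG00000116048.1, GRCm38 chromosome 1, 93478993 to 93509733, plus strand) the log2 change was 1.10 (SE 0.107, limma adjusted p = 0.00832). A longer Septin2 record on the same strand (ENSMUSG00000026276.20, chromosome 1, 93478964 to 93510260) covers it, and all 3335 exonic bases of the shorter record are also exonic in the longer one, which has 7979. The longer record stood at 94.0 ± 9.45 TPM in saline and 66.3 ± 6.05 TPM in rmPRL (SD, n = 5 each), lower in all 5 rmPRL libraries than in all 5 saline libraries, with a log2 difference of -0.50 that missed the threshold (limma adjusted p = 0.0796). The sum of both records was 125 ± 12.5 TPM in saline and 133 ± 12.9 TPM in rmPRL (SD, n = 5 each), a log2 difference of 0.10 within the spread between libraries (two-sided exact permutation test, p = 0.262). The shorter record held 24.5% ± 0.578 of that sum in saline and 50.1% ± 3.89 in rmPRL (SD, n = 5 each).

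**Figure D1:**
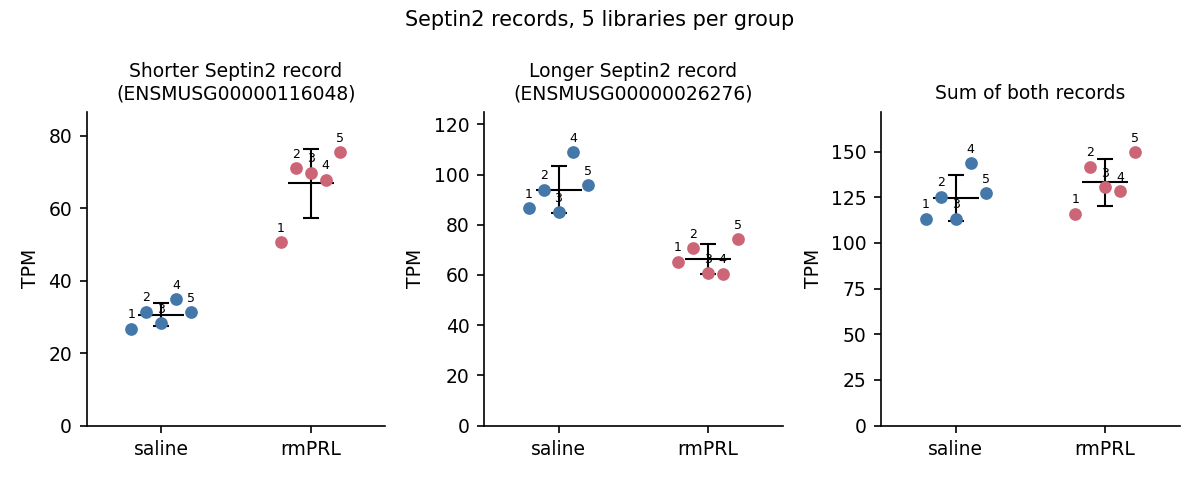
TPM of the shorter Septin2 record, the longer Septin2 record and their sum in each library (points, numbered by replicate) of the saline and rmPRL groups, with group means and SD (bars, n = 5). The shorter record was at 50.6 TPM or above in rmPRL and at 34.9 TPM or below in saline, the longer record was lower in rmPRL, and the sums of the groups overlapped.

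Gm17066 and Gm22581 were outside the naming rule and were chosen after their values were seen. Gm17066 (ENSMUSG00000091509.7, chromosome 14, 105109390 to 105114676), a processed transcript on the strand of Rbm26 and overlapping that gene, rose from 16.1 ± 0.878 to 24.9 ± 2.19 TPM (SD, n = 5 each), a log2 change of 0.59 (limma adjusted p = 0.0196). Gm22581 (ENSMUSG00000065669.1, chromosome 3, 96724265 to 96724400), annotated as a small nucleolar RNA inside Polr3c on the same strand, fell (limma adjusted p = 0.0165). It was listed at 0 in all 5 rmPRL libraries and at 1.23, 3.50, 2.88, 4.79 and 4.94 TPM in saline libraries 1 to 5. These are low values with no spread in rmPRL, so the size of the fall depends on the pseudocount, and its counting error is unknown. The library kit was one for mRNA, and whether the reads came from the small nucleolar RNA was not tested. Both Gm17066 and Gm22581 lie within a gene on their own strand, so their values depend on how reads were assigned between overlapping genes. Neither passed without saline 3, saline 5, rmPRL 2 or rmPRL 5, where the shorter Septin2 record alone passed, nor without rmPRL 4. Gm17066 also did not pass without saline 1 (limma adjusted p = 0.0607) or with GC content and length trends removed (0.0661, log2 change 0.41). Neither passed with the replicate number as a block (0.172 for Gm17066 and 0.113 for Gm22581), with the fibroblast and matrix score as a covariate (0.0998 for both) or without both libraries with high luteal markers (0.126 and 0.112); the last pair of settings and the GC content correction were chosen after the data were seen. Over all alternatives the log2 change of Gm17066 ran from 0.41 to 0.65. That of Gm22581 ran from -5.01 (with a pseudocount of 0.1) to -1.95. Over all genes, 7 passed without rmPRL 3 and 18 without rmPRL 1. The count was 0 with no filter on low values (limma, 3276 genes at an unadjusted p under 0.05), 270 with array weights, which weight libraries by how closely they follow their group, and 242 with saline 1 and rmPRL 3 both left out, a pair picked after the data were seen because exchanging their labels gave the most genes.

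Below the threshold, the genes with the smallest p whose groups did not overlap were Hnrnpa0, Gt(ROSA)26Sor and Tmem126a on the higher side. Hnrnpa0, an RNA-binding protein of heterogeneous nuclear ribonucleoproteins, was at 116 ± 7.01 TPM in saline and 158 ± 14.0 TPM in rmPRL (SD, n = 5 each), a log2 difference of 0.44 (limma adjusted p = 0.0784). The log2 differences of Gt(ROSA)26Sor and Tmem126a were 0.40 and 0.39 (limma adjusted p = 0.0935 and 0.117). On the lower side, Kmt2e, a member of the KMT2 family of chromatin regulators, was at 41.5 ± 2.59 TPM in saline and 30.0 ± 2.45 TPM in rmPRL (SD, n = 5 each), a log2 difference of -0.46 (limma adjusted p = 0.0678). Sem1, a small subunit of the proteasome, was at 295 ± 11.4 and 209 ± 25.5 TPM (SD, n = 5 each), and Scand1 at 27.0 ± 2.52 and 17.2 ± 2.75 TPM (SD, n = 5 each), with limma adjusted p = 0.0784 for both. Snora5c, a small nucleolar RNA inside Tbrg4, was listed at 0 in 4 rmPRL libraries and at 1.69 TPM in rmPRL library 4, against 2.44 to 4.63 TPM in saline (limma adjusted p = 0.0784). With single libraries left out the limma adjusted p ran from 0.0115 to 0.305 for Hnrnpa0, 0.00328 to 0.305 for Sem1 and 0.00874 to 0.305 for Scand1, lowest without rmPRL library 1 and highest without rmPRL library 4. It ran from 0.0345 (without rmPRL library 3) to 0.21 for Kmt2e and from 0.00154 (without rmPRL library 4) to 0.219 for Snora5c.

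Across the tested genes, 2588 (16.0%) had an unadjusted p under 0.05, where 5% would be 807 genes; 990 were higher and 1598 lower in rmPRL. This balance depended on the scaling: 61.7% of these genes were lower with TPM as deposited and 43.3% were lower after TMM scaling, 47.5% after quantile normalization and 47.1% after rescaling without mitochondrial genes and the 50 highest genes. The groups did not overlap for 495 genes (3.07%), against 0.794% by chance. At an adjusted p under 0.1 there were 17 genes, and under 0.2 there were 465 (limma). Over the alternatives the count at an unadjusted p under 0.05 ran from 1360 with the fibroblast and matrix score as a covariate to 4310 with array weights. It was 4154 with saline 1 and rmPRL 3 both left out. The covariate and that pair were chosen after the data were seen.

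**Figure D2:**
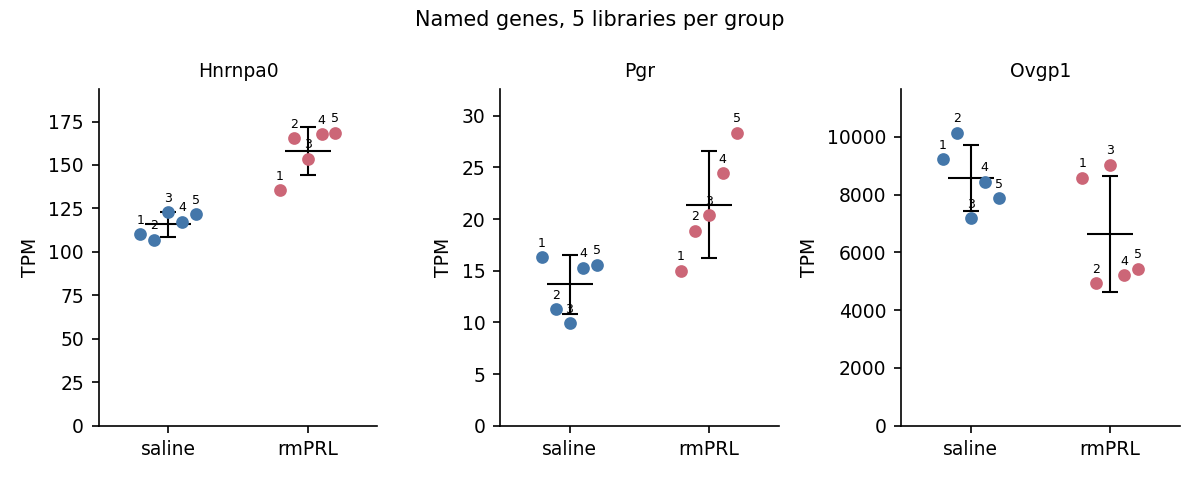
TPM of Hnrnpa0, Pgr and Ovgp1 in each library (points, numbered by replicate) of the saline and rmPRL groups, with group means and SD (bars, n = 5). Hnrnpa0 did not overlap between the groups, while Pgr and Ovgp1 did.

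The prolactin receptor itself was low in this tissue. Prlr (ENSMUSG00000005268.20, chromosome 15, 10177238 to 10349180, plus strand) lay between 0.475 and 0.908 TPM in 8 libraries and stood at 3.96 TPM in saline library 4 and 3.11 TPM in rmPRL library 2, so it did not meet the filter for the gene test. The groups differed by 0.05 on the log2(TPM + 1) scale (two-sided exact permutation test, p = 0.81), and the difference was -0.21 without rmPRL library 2 and 0.39 without saline library 4. The same libraries had the highest values of ovarian steroid-making genes: Cyp11a1, which starts steroid synthesis from cholesterol, was at 135 TPM in saline library 4 and 125 TPM in rmPRL library 2, and at 6.27 TPM or below elsewhere. Of the transducers on the list, Jak2 was at 77.0 ± 7.55 and 69.4 ± 3.74 TPM, Stat5a at 32.4 ± 8.99 and 38.4 ± 9.16 TPM and Stat5b at 27.9 ± 2.91 and 30.1 ± 2.73 TPM in saline and rmPRL (SD, n = 5 each), and none of the 9 tested members of the list passed the threshold over all genes or adjusted over the list alone (limma).

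**Figure D3:**
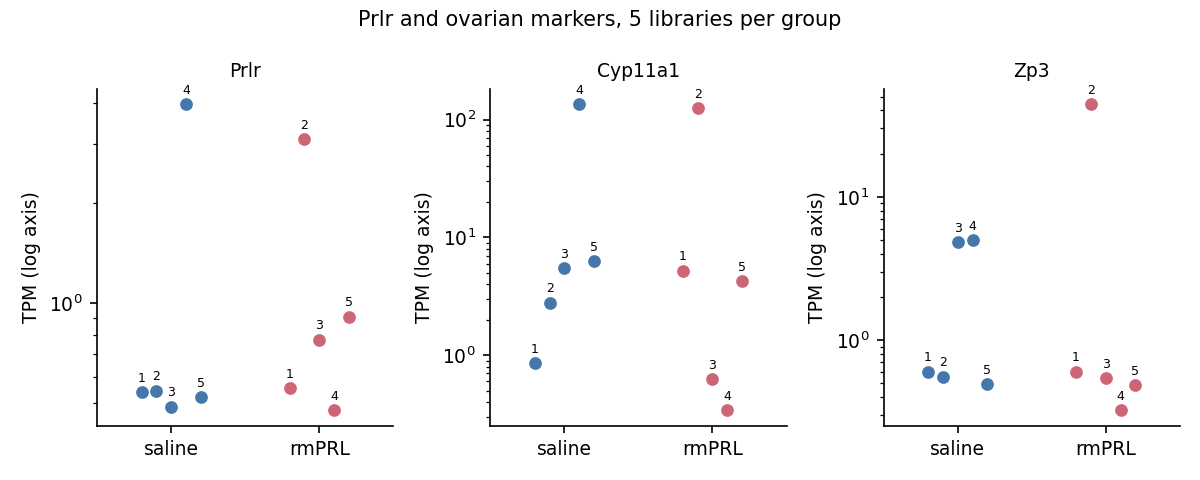
TPM of Prlr, Cyp11a1 and Zp3 in each library on log axes (points, numbered by replicate), by group (n = 5). Saline library 4 and rmPRL library 2 held the highest values of all 3 genes.

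Of the genes that STAT5 is known to induce, Cish and Socs2 did not pass the threshold, and Igf1 passed only adjusted over its list. Cish, a feedback inhibitor that prolactin induces in many cells, was at 1.81 ± 0.462 TPM in saline and 2.29 ± 0.496 TPM in rmPRL (SD, n = 5 each), a log2 difference of 0.23 with a 95% interval from -0.07 to 0.54 (limma adjusted p = 0.411). That difference was 0.15 without rmPRL library 2 and ran from 0.12 to 0.34 over all alternatives. Socs2, another such inhibitor, was at 64.5 ± 7.57 and 68.2 ± 12.3 TPM (SD, n = 5 each; log2 difference 0.07, 95% interval from -0.20 to 0.34, limma adjusted p = 0.797). Of the 12 tested members of the STAT5 target list, 0 passed over all genes and 1 passed adjusted over the list alone (limma). That member was Igf1, insulin-like growth factor 1, at 20.5 ± 5.40 TPM in saline and 44.4 ± 18.3 TPM in rmPRL (SD, n = 5 each; log2 difference 1.02, SE 0.267, limma adjusted p = 0.18 over all genes). The list as a whole had an adjusted p of 0.75 in the limma camera test with an estimated correlation. Milk protein genes were near 0: Csn1s1, Csn2 and Wap were listed at 0 in every library, and Xdh, the only member of that list past the filter, was at 21.6 ± 4.11 and 21.7 ± 3.16 TPM (SD, n = 5 each).

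Among steroid receptors and the genes they induce, Pgr and Igf1 had higher means in rmPRL. Pgr, the progesterone receptor and an estrogen-induced gene, was at 13.7 ± 2.87 TPM in saline and 21.4 ± 5.14 TPM in rmPRL (SD, n = 5 each), a log2 difference of 0.60 (SE 0.176, limma adjusted p = 0.199 over all genes). Pgr and Igf1 were the 2 of 12 tested estrogen-induced genes that passed adjusted over the list alone, and 0 passed over all genes (limma). With the fibroblast and matrix score as a covariate, a setting chosen after the data were seen, the log2 difference was 0.34 for Pgr and 0.64 for Igf1. Pgr was also the only member of 8 tested steroid receptors and enzymes to pass adjusted over the list alone. Esr1, the estrogen receptor alpha, was at 156 ± 19.1 and 158 ± 21.4 TPM (SD, n = 5 each; log2 difference 0.02, limma adjusted p = 0.937). Of the growth factors and receptors, 4 of 20 tested members passed adjusted over the list alone and 0 over all genes (limma). Vegfa, which promotes vessel growth, was higher with Igf1, at 80.5 ± 6.42 TPM in saline and 93.9 ± 6.07 TPM in rmPRL (SD, n = 5 each). The receptors Erbb3, at 44.9 ± 5.71 and 31.6 ± 5.19 TPM, and Igf1r, at 42.5 ± 4.64 and 34.7 ± 2.33 TPM (SD, n = 5 each), were lower.

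Markers of the oviduct's epithelial cells did not pass the threshold. Ovgp1, the oviduct-specific glycoprotein of secretory cells, was at 8573 ± 1148 TPM in saline and 6635 ± 2001 TPM in rmPRL (SD, n = 5 each), a log2 difference of -0.41 (SE 0.182, limma adjusted p = 0.306). It was at 8589 and 9034 TPM in rmPRL libraries 1 and 3 and at 4923, 5198 and 5432 TPM in rmPRL libraries 2, 4 and 5. Pax8, a transcription factor of secretory cells, was at 91.4 ± 3.46 and 82.2 ± 22.8 TPM (SD, n = 5 each), with a log2 difference of -0.20 (limma adjusted p = 0.555). That difference was -0.046 without rmPRL library 2 and -0.32 without rmPRL library 1. Foxj1, the regulator of motile cilia, was at 689 ± 113 and 741 ± 48.2 TPM (SD, n = 5 each), with a log2 difference of 0.12 (limma adjusted p = 0.585). That difference was 0.041 without saline library 1 and 0.18 without saline library 3. Of 10 general epithelium genes, 8 had a lower mean in rmPRL, with a mean log2 difference of -0.12, and 3 were lower at an unadjusted p under 0.05; 0 passed over all genes or adjusted over the list alone (limma), and the list had an adjusted p of 0.81 in the camera test with an estimated correlation. Of 30 tested genes of motile cilium structure, 28 had a mean below that of saline (25 after TMM scaling), 0 passed over all genes or adjusted over the list alone, and the list had an adjusted p of 0.91 in the camera test with an estimated correlation. Of 14 ciliogenesis regulators, 5 had higher and 9 lower means in rmPRL, 2 and 4 of them at an unadjusted p under 0.05, and 0 passed in either way (limma). Mcidas, which starts multiciliated cell formation, was at 4.90 ± 2.37 and 2.25 ± 0.626 TPM and Gmnc, its upstream regulator, at 8.46 ± 1.04 and 10.9 ± 1.91 TPM (SD, n = 5 each).

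Genes of antigen presentation by MHC class II had the smallest p of the lists in the camera test with an estimated correlation. Mitochondrially encoded genes had the smallest in the exact test of list scores. All 8 tested MHC class II members had higher means in rmPRL, with a mean log2 difference of 0.24, yet the camera test with an estimated correlation gave an adjusted p of 0.75 (unadjusted 0.0751), and the exact permutation test of the list score gave p = 0.0238 before and 0.548 after adjustment over 46 lists (two-sided). Adjusted over the list alone, 5 members passed, and 0 passed over all genes (limma): Cd74, at 194 ± 26.2 TPM in saline and 238 ± 13.1 TPM in rmPRL, H2-Ab1, at 77.3 ± 12.5 and 97.3 ± 8.07 TPM (SD, n = 5 each), H2-Aa, H2-Eb1 and H2-Oa. With the fibroblast and matrix score as a covariate the log2 difference went from 0.30 to 0.19 for Cd74 and from 0.34 to 0.20 for H2-Ab1. Without both libraries with high luteal markers it went from 0.21 to 0.13 for H2-Aa and from 0.24 to 0.17 for H2-Eb1. These settings were chosen after the data were seen. Macrophage and monocyte markers lay on the same side, with 12 of 13 members above saline and a mean log2 difference of 0.28 (adjusted p of 0.75 with an estimated correlation); Mrc1 was at 4.73 ± 1.33 and 7.19 ± 1.82 TPM (SD, n = 5 each). Fibroblast and matrix genes had a mean log2 difference of 0.44, with 15 of 16 above saline, and all 16 cholesterol synthesis genes were above saline (adjusted p of 0.75 with an estimated correlation for both).

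Of 50 lists fixed before the data were examined, 46 had at least 3 tested members, and 0 of these passed in the camera test with an estimated correlation (0 had an unadjusted p under 0.05). With a preset correlation of 0.01 camera called 10: MHC class II, cholesterol synthesis, macrophage and monocyte, fibroblast and matrix, mitochondrially encoded, endothelium, complement, S phase and smooth muscle genes were higher, and motile cilium structure was lower. None of these calls held with an estimated correlation (adjusted p from 0.75 to 0.91). The rotation test fry called 0 lists as moving on balance one way (2 at an unadjusted p under 0.05) and 1, mitochondrially encoded genes, as changing in either direction. The exact permutation test of the list scores called 0 (2 at an unadjusted p under 0.05, smallest adjusted p = 0.365). With single libraries left out it also called 0. The lists at an unadjusted p under 0.05 then ran from 1 without rmPRL library 2 to 8 without saline library 1. Of 88 ribosomal protein genes 0 passed over all genes or adjusted over the list alone (limma), and of 10 mesothelium markers 1 passed adjusted over the list alone, Lrrn4, at a log2 difference of 0.52. None of the 562 genes tested on the lists passed over all genes. For 6 lists the median, the mean and the test differed in sign.

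**Figure D4:**
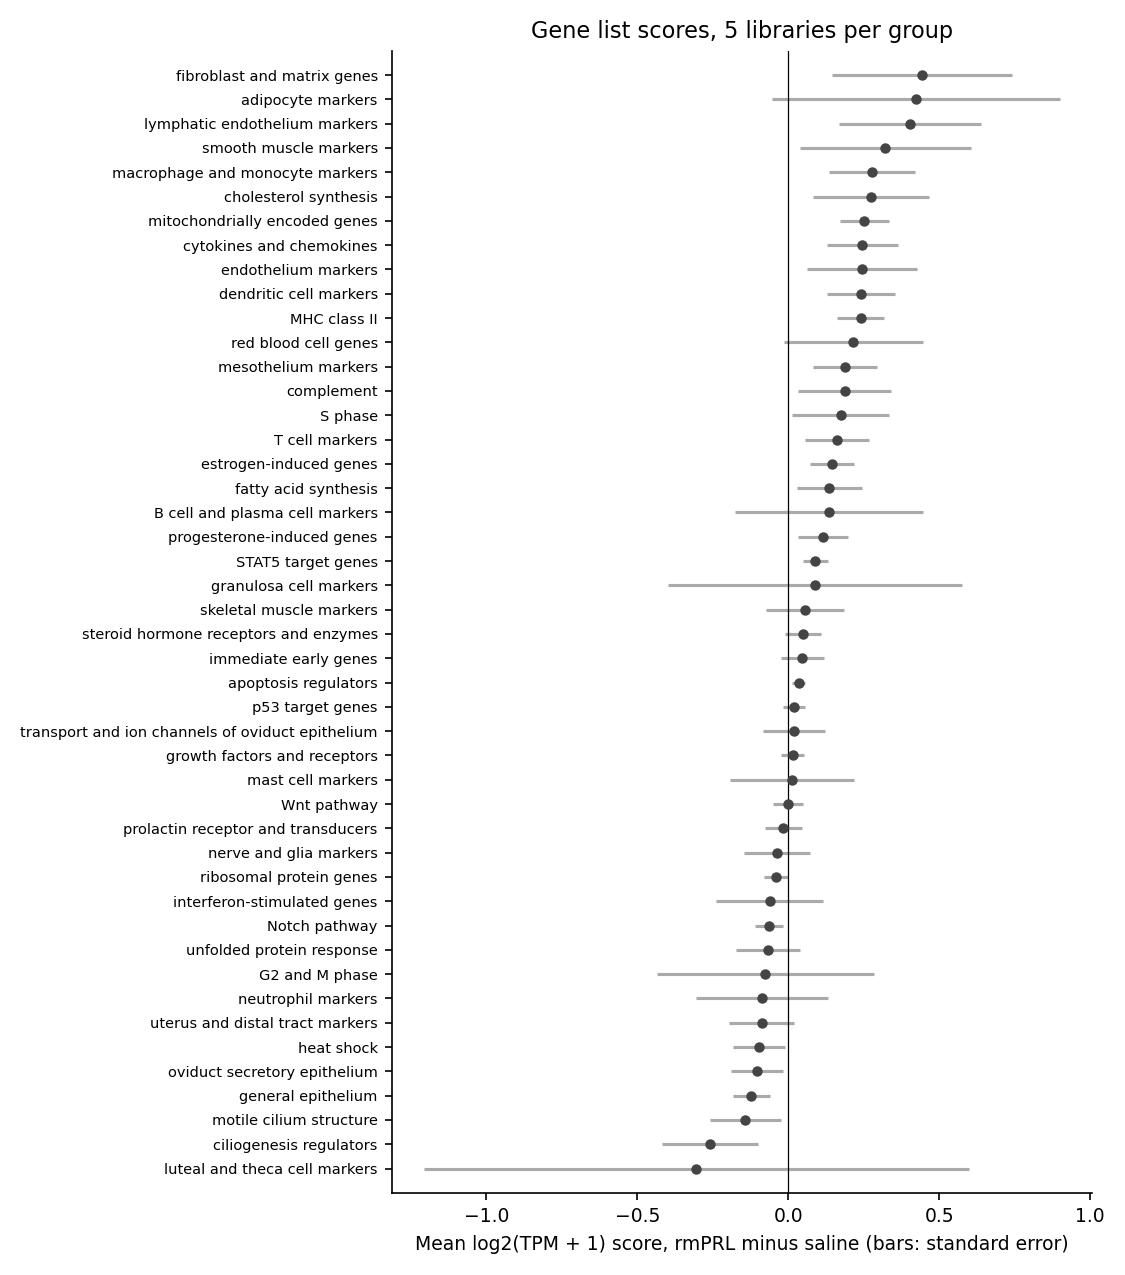
Mean log2(TPM + 1) score of each of 46 gene lists, rmPRL minus saline (points), with standard errors from 5 libraries per group (bars). Of the 46 lists, 30 lay above 0 and 16 below, and none passed the test with an estimated correlation.

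Mitochondrially encoded transcripts took 5.25% ± 0.292 of the TPM in saline and 6.64% ± 0.484 in rmPRL (SD, n = 5 each), higher in all 5 rmPRL libraries than in all 5 saline libraries (two-sided exact permutation test, p = 0.00794, the smallest it can give). The largest part of the difference came from mt-Atp8, a short gene for a subunit of ATP synthase that overlaps mt-Atp6, at 6298 ± 906 TPM in saline and 15494 ± 5094 TPM in rmPRL (SD, n = 5 each; log2 difference 1.23, limma adjusted p = 0.119, from 0.00328 without rmPRL library 1 to 0.311 without rmPRL library 4). The overlapping mt-Atp6 was at 1196 ± 158 TPM in saline and 1524 ± 400 TPM in rmPRL (SD, n = 5 each), a log2 difference of 0.32 (limma adjusted p = 0.381). The values of mt-Atp8 and mt-Atp6 depend on how reads were assigned between them, which was not tested. Without mt-Atp8 the share was 4.62% ± 0.205 and 5.09% ± 0.224 (SD, n = 5 each, two-sided exact permutation test, p = 0.0238). Of 15 tested mitochondrially encoded genes, mt-Nd1, mt-Nd3, mt-Co3 and mt-Atp8 passed adjusted over the list alone and 0 over all genes (limma), while mt-Co1 was at 13412 ± 451 and 13558 ± 571 TPM (SD, n = 5 each). With GC content and length trends removed the log2 difference went from 0.53 to 0.33 for mt-Nd3, from 0.38 to 0.30 for mt-Nd1 and from 1.23 to 0.97 for mt-Atp8. Without both libraries with high luteal markers it went from 0.67 to 0.43 for mt-Co3. These settings were chosen after the data were seen. The camera test with an estimated correlation gave an adjusted p of 0.75 for the list.

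**Figure D5:**
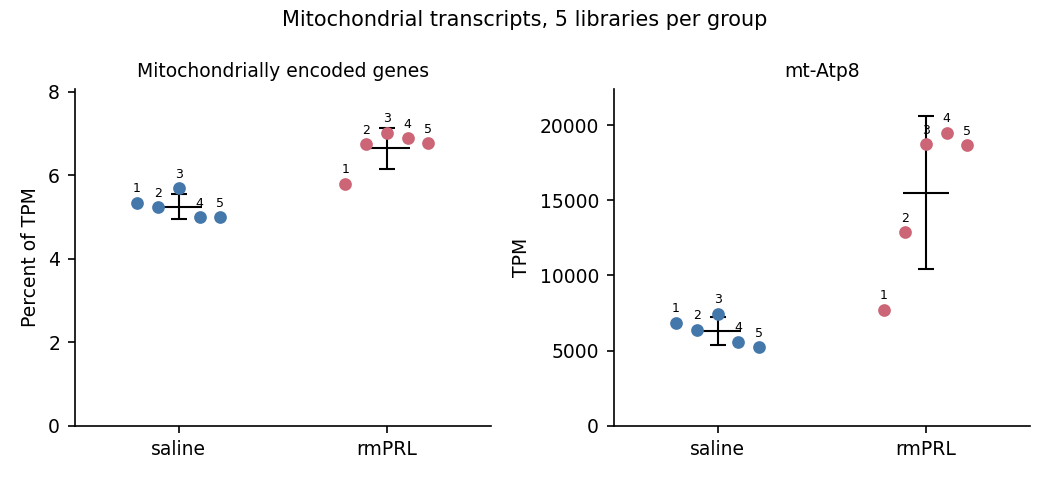
Percent of TPM from mitochondrially encoded genes and TPM of mt-Atp8 in each library (points, numbered by replicate) of the saline and rmPRL groups, with group means and SD (bars, n = 5). For both measures rmPRL library 1 lay nearest the saline libraries, at 5.79% and 7716 TPM.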

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

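The tests of the exchanged labels, of the Septin2 records, of ovarian RNA, of GC content and length and of the fibroblast covariate were chosen only after the results were seen; the splits of the samples were planned.

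A library lay far from the other 4 of its group in 9 of 170 groups examined (named genes, list scores and library measures), where chance alone gives about 8.5, or 1 in 20. For Septin2 (the shorter record) rmPRL library 1 was at 50.6 TPM against 67.9 to 75.3 TPM in the other rmPRL libraries, and for the share of mitochondrial transcripts the same library was at 5.79% against 6.74% to 7.01%. Kmt2e was at 46.1 TPM in saline library 2 against 39.7 to 41.3 TPM, Snora5c at 1.69 TPM in rmPRL library 4 against 0 in the others, and Esr1 at 121 TPM in rmPRL library 2, the diestrus library, against 159 to 175 TPM. The mast cell list score, centred on the mean of all libraries, was -0.56 in saline library 3 against -0.00045 to 0.22.

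Prlr was at 3.96 TPM in saline library 4, against 0.487 to 0.544 TPM in the other saline libraries, and at 3.11 TPM in rmPRL library 2, against 0.475 to 0.908 TPM, and the granulosa list score was 1.76 in rmPRL library 2 against -0.55 to -0.17 in the other rmPRL libraries. Saline library 4 and rmPRL library 2 held the highest values for 8 of the 8 luteal and theca markers that reached 1 TPM in any library, against 6.41% of 18624 other genes (Fisher's exact test, p = 2.94e-10); of these 8 markers, 3 were at 1 TPM or more in every other library too, and none was on another list. The same held for 13 of 13 oocyte markers and for 6 of 10 granulosa markers, with Zp3 at 44.1 TPM in rmPRL library 2, 5.00 TPM in saline library 4 and 4.81 TPM in saline library 3. Fisher's test treats genes as independent, while tested luteal and theca markers varied together between libraries (estimated correlation 0.78). Its p therefore overstates the evidence, which rests on 2 pools picked for their high Prlr. Ovarian RNA in these pools may account for their Prlr values, since the infundibulum lies against the ovary. The diestrus stage of rmPRL library 2 stays open for that library, untested, while saline library 4 was labelled proestrus.

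The shorter and longer Septin2 records moved in opposite directions while their summed TPM differed by 0.10 on the log2 scale. Since every exonic base of the shorter record lies in the longer one, a shift in how reads were divided between overlapping records may account for the rise of the shorter record without a change in Septin2 as a whole. Whether the shift came from transcript use under rmPRL or from the assignment of reads was not tested, as both would leave the sum in place.

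Of 100 splits of the 10 libraries into groups of 5, 2 gave 4 or more genes past the threshold, the real one included. That is below the bound of 5 set beforehand. A count of 4 genes is small, however, and the highest other split gave 344, so this does not exclude chance. The 2588 genes at an unadjusted p under 0.05 were matched or exceeded by 5 of 100 splits (highest other 4093), so chance was not excluded for them. For the lists the real count was 0, which all 100 splits had to reach (highest other 1), so the splits tested nothing there. The split with 344 genes is the one by label with saline library 1 and rmPRL library 3 exchanged; it was the highest of those drawn, and its count alone names no cause.

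For the 2588 genes by label, removing trends with GC content and transcript length gave 1.01 times as many, which argues against such trends as their whole cause; with the fibroblast and matrix score as a covariate the count was 0.526 of that number, between the bounds set for and against a differing stromal share, which stays open. An exchange of labels also stays open. The exchanged split separated 1108 genes and the split by label 495, which put the split by label at rank 5 among all splits. The split by label is itself among the 25 splits 1 exchange away from the exchanged one. Of these 25, 3 separated as many genes as the split by label, itself counted (highest other 664). Other values ran with the labels in these libraries: the shorter Septin2 record, called by label, was at 26.8 TPM in saline library 1 and 69.8 TPM in rmPRL library 3, and the mitochondrial share was 5.34% and 7.01%. That record and that share were given because they lay apart by label, so they are no independent evidence against an exchange. None of the 4 called genes was among the 344. Genes called by label differ between the labelled groups and could hardly pass with those labels exchanged, so this says nothing about an exchange. Effects of rmPRL and of animal pools remain possible, untested.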

How the results depend on the processing

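The settings without both libraries with high luteal markers, without saline 1 and rmPRL 3, with a GC content and length correction, with a fibroblast covariate and without mt-Atp8, the list tests under the scalings, and the library counts, mitochondrial share and list scores with single libraries left out were chosen after seeing the data; the others were planned. Of 36 genes followed, 33 kept their direction in all alternatives run, as did the 13 lists followed by name. Apart from the genes that were always named, these genes were named for their differences, so a kept direction is little evidence for them. The 3 that reversed, Prlr, Esr1 and Socs2, were among the genes always named. The 4 genes past the threshold became 0 with no filter on low values (more genes tested), 270 with array weights (0.475 for saline library 1 to 2.44 for saline library 5), 1 with the fibroblast covariate, 2 with the replicate block, and 1 to 18 when single libraries were left out; other settings, apart from the pair named next, gave 3 to 5. Gm17066 lost its call with the GC content and length correction (adjusted p = 0.0661). Gm17066 and Gm22581 lost theirs with the replicate block (0.172 and 0.113), the fibroblast covariate (0.0998 for both) and without both libraries with high luteal markers (0.126 and 0.112). Over all alternatives the log2 changes of Gm17066 and Gm22581 ran from 0.41 to 0.65 and from -5.01 to -1.95. With saline 1 and rmPRL 3 both left out 242 genes passed (50 higher, 192 lower, the 4 genes among them). These libraries were picked because exchanging their labels gave the highest count of the splits drawn, so that choice favours a high count, and 242 is no independent evidence of an effect of rmPRL. Same-numbered libraries did not deviate together (correlations from -0.25 to 0.11, with 1 of 5 best matched by its own number). These values show no shared deviation by number, but cannot tell whether same-numbered pools were handled together. Lists past the threshold numbered 10 with the preset correlation, 1 with fry for changes in either direction (mitochondrially encoded genes) and 0 otherwise. Some directions reversed. Esr1 was -0.018 with array weights, -0.037 without saline 1 and rmPRL 3 and -0.018 to 0.11 with single libraries left out; Socs2 was -0.011 with array weights, -0.031 with the fibroblast covariate and -0.0056 to 0.14 with single libraries left out. Prlr, at 0.05 with all libraries, ran from -0.21 to 0.39, and the difference in genes at 1 TPM, 4.6 with all libraries, from -95.2 to 61.3, both wider than the differences themselves. The Prlr range comes from saline 4 and rmPRL 2, which held its highest values; the other causes were not tested. DESeq2 and edgeR were planned for counts and not run on TPM. Depth is unknown, so low genes have no counting error.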

Other observations

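The genes given here were chosen after their values were seen. Adam28 and Igkv10-96 did not follow the treatment or stage labels in every library. Adam28 was at 17.4 TPM in saline library 1 and 23.4 TPM in rmPRL library 3, with 22.4 to 23.4 TPM in the other saline libraries and 11.8 to 14.6 TPM in the other rmPRL libraries. Saline library 1 thus lay between the other saline and the other rmPRL libraries. Adam28 was picked from the genes with the smallest p in the split with saline library 1 and rmPRL library 3 exchanged. Its values are therefore no independent evidence of an exchange. The immunoglobulin segment Igkv10-96 was at 19.3 TPM in saline library 1 and at 20.4, 26.7 and 20.1 TPM in rmPRL libraries 1, 2 and 4, and at 2.30 TPM or below in the other 6. Upk1a, a urothelial marker on the kidney and urinary tract list, had means of 47.1 TPM in saline and 46.9 TPM in rmPRL (n = 5 each) and a log2 difference of 0.16 (SE 0.601), with the other 7 members of that list below the filter. Klrd1, the only natural killer cell marker past the filter, was at 0.912 ± 0.312 and 1.87 ± 0.483 TPM (SD, n = 5 each; log2 difference 0.58, limma adjusted p = 0.175).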
